A study of Rattus norvegicus with 3 samples.

How the data were processed

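RNA from the parotid, submandibular and sublingual glands of male Wistar rats was measured on 3 arrays, 1 per gland. Per the labels' protocols, pieces of gland were kept in an RNA-preserving solution, total RNA was extracted with a column kit, and 500 ng was amplified and labelled with Cy3. Samples were grouped by the gland named in their labels. The array with the submandibular label is called submandibular-labelled, because none of its granular duct products stood 4-fold above both other arrays; its group was not changed.

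Per the file headers, the deposited intensity values per spot (processed signal, mean signal, SD of the spot's pixels and local background) came from Agilent Feature Extraction 10.1.1.1 with the protocol GE1-v5_10_Apr08 on array design 014879, with coordinates in rn4. The headers also state that spatial and multiplicative detrending were on, local background correction was off, and low signals were replaced by surrogates. Other deposited columns are flags of 0 or 1 per spot (well above background, saturated, outlier). The series' value table holds a linear ratio per spot made by the authors; its making is not given in the sources used here. Set against the scanner values of 43379 spots per array, it equals the processed signal divided by 1 number per array (190, 236 and 250 for parotid, submandibular-labelled and sublingual), with a range of at most 0.0142 on the log2 scale for spots above 1000. Its medians are 0.152, 0.122 and 0.128, no gene was centred, and its scale and direction are settled by that match.

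The main values are log2 of the processed signal minus each array's 75th percentile over probes (signals of 186, 228 and 244). Control spots and spots with an outlier flag (68, 79 and 73) were left out, and spots of 1 probe were averaged on the log2 scale. No spot was saturated. The lowest probe well above background lay at -3.43, -3.58 and -3.74. Where 1 side was not well above background, the fold is the bright level against the higher of that lowest level on the dim array and the dim probe's own level. It is then a lower bound under this processing. No fold is given where both sides were dim or the bound was under 1.

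Of 41012 probes, 20648 were matched to 1 gene of the RefSeq table of assembly GRCr8, used for names only: 11044 by accession, 4993 by symbol, 3351 by an older symbol, 1037 by gene identifier and 223 by the symbol in the description. These gave 16144 genes, of which 16140 had a probe left once spots with an outlier flag were left out. The unmatched probes enter no comparison except where stated. A gene with several probes (3644 genes) was represented by the probe with the highest mean level. Probes of 23, 18 and 1 genes disagreed in direction by at least 2-fold between the submandibular-labelled and parotid, sublingual and parotid, and sublingual and submandibular-labelled arrays, and none of these is a gene named by its rank. Coordinates are those of the probes in the files.

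With 1 array per gland no test was made. Counts are of genes at least 4-fold apart, per pair of arrays and for each array against both others. The median of each of 22 gene lists is placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays; members with no matched probe were not analysed here, and some members are not reported here. The only error in the design is that of repeat spots: 178, 168 and 171 probes had at least 3 unflagged spots well above background. All arrays lay on 1 slide and 1 scan, so slide and scan do not separate the glands, while gland and position on the slide cannot be told apart. The lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per pair and direction, the 10 genes with the largest bounded fold of at least 4, per gland the 10 with the largest smaller fold against both others, genes with a symbol only, and up to 6 members of each list by size of difference, with 1 marker where a list is explained.

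Scaling matters for the comparisons with the parotid. Over genes well above background on all 3 arrays, the median difference was 0.14 for submandibular-labelled minus parotid and 0.11 for sublingual minus parotid. Centring on each array's median instead raised these by 0.31 and 0.24. The alternatives were normexp background correction (offset 50, limma 3.58.1 in R 4.3.3), quantile normalization, median centring, the deposited ratio values, other filters and bounds, the median of a gene's probes, probes instead of genes, and thresholds of 2-fold and 10-fold. The values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

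The counting and list steps were tested on simulated data, made from 1 real array with known changes put into 1 simulated array. In the simulated comparison of sublingual with parotid (16144 genes), all 50 genes raised 8-fold and all 50 lowered 8-fold were called at 4-fold, and none of the 50 raised and 50 lowered 2-fold. None of 10232 unchanged genes was called. The added noise was far under 4-fold, so this last count was fixed in advance. All simulated arrays kept the background and outlier flags of the real one, so lower bounds and uneven spots were not tested. A list of 20 genes raised 2-fold lay at percentile 100 and a list of 20 unchanged genes at percentile 71.9.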

Results

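Gene expression was measured in the 3 major salivary glands of the rat, the parotid, submandibular and sublingual glands. Total RNA from the glands of male Wistar rats, 10 weeks old, was labelled with Cy3 and hybridised to 1 Agilent rat array per gland. The series' design text speaks of 3 rats, and no source used here says which animal or animals each array stands for. There are therefore no replicates: each value below describes 1 array, no p-value is given, and the number of arrays limits the precision. The 3 arrays lay on 1 slide and came from 1 scan. Of 16140 genes, 64.6% were well above background on the parotid array, 62.8% on the submandibular-labelled array and 63.9% on the sublingual array, and no spot was saturated. Levels are log2 signals relative to each array's 75th percentile. Where the dimmer side was not well above background, the fold is a lower bound under the main processing and is written "at least". Spots of the same probe within an array had a median SD of 0.09 (parotid), 0.08 (submandibular-labelled) and 0.09 (sublingual) on the log2 scale, which covers neither animals nor labelling.

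The design asks how the 3 glands differ. The parotid array stood apart from both other arrays, and the submandibular-labelled and sublingual arrays were almost alike. The labels alone say which gland is on which array; "submandibular-labelled" is written throughout because none of 22 probed products of the submandibular granular convoluted ducts, 11 of them well above background there, was at least 4-fold higher on that array than on both other arrays. Across 9515 genes well above background on all 3 arrays, the log2 levels of the submandibular-labelled and sublingual arrays correlated with r = 0.991. The correlation with the parotid array was 0.920 for the submandibular-labelled array and 0.919 for the sublingual array. These correlations run across genes, which are not independent replicates. A difference of at least 2-fold was measured for 1832 of these genes (19.3%) between the submandibular-labelled and parotid arrays and for 2100 (22.1%) between the sublingual and parotid arrays. Between the submandibular-labelled and sublingual arrays it was measured for 109 genes (1.15%).

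**Figure D1:**
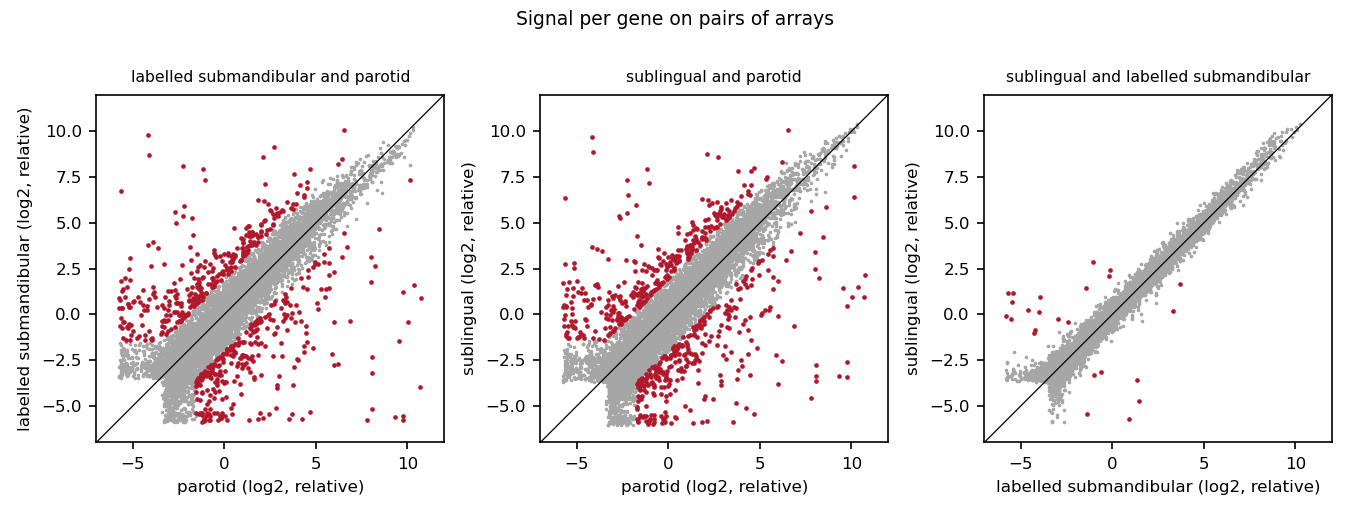
Level of each gene (log2, relative to the array's 75th percentile) on 1 array against another, for genes well above background on at least 1 of them. Red points are at least 4-fold apart, with dim values held at the lowest well-measured level, and the line marks equal levels. The right panel (submandibular-labelled and sublingual) has 24 red points, against 313 and 304 (left) and 332 and 312 (middle) above and below the line in the panels with the parotid array.

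On the submandibular-labelled array, genes of mucus production were far above their parotid level and serous secretory products were far below it. Muc19, a gel-forming mucin, was at least 9628-fold higher than in the parotid, and Agr2, a protein disulfide isomerase of mucin-producing cells, at least 4544-fold higher. Dnase1, a secreted nuclease, was at least 20024-fold higher in the parotid, and Amy1, salivary amylase, was 942-fold higher there. The sizes depend on the processing. Over the choices tried, the log2 difference from the parotid ranged from 10.965 to 13.987 for Muc19 (13.233 in the main analysis). It ranged from -14.697 to -11.865 for Dnase1 (-14.289) and from 8.303 to 12.393 for Bglap (10.153). In all, 313 of 10916 compared genes were at least 4-fold higher on the submandibular-labelled array and 304 at least 4-fold higher on the parotid array. Of these folds, 77 and 103 are lower bounds. With normexp background correction the counts were 196 and 134, and with centring on the median 435 and 214.

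The 10 genes with the largest folds over the parotid were Muc19, Agr2, Kcne1, Bglap, Sel1l3, Bpifb2, Bcas1, Ddc, Kntc1 and Fam3d. Kcne1, an accessory subunit of potassium channels, was 1317-fold higher. Bglap, whose protein osteocalcin is known from bone matrix, was at least 1138-fold higher. Sel1l3 was 545-fold higher (a log2 difference of 9.09, and of 6.30 with the median of its probes) and Bpifb2, a protein of the BPI fold family, 345-fold higher. Bcas1 was 319-fold higher, and Ddc, the decarboxylase of aromatic amino acids, 280-fold higher. Kntc1 was 205-fold and Fam3d 196-fold higher. In rn4 coordinates, as the files give them for the probes, the Muc19 probe lay on chromosome 7 from 130416247 to 130416899 and the Agr2 probe on chromosome 6 from 54709562 to 54710914. Whether a probe lay in an exon or UTR was not examined.

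The 10 genes with the largest folds in the other direction were Dnase1, Smr3a, Cst5, Prp25l1, Prp2, Amy2a3, Zfp831, Crisp3, Amy2-ps2 and Aplnr. Smr3a was at least 10461-fold, Cst5, a cystatin, at least 10204-fold and the proline-rich protein gene Prp25l1 at least 7766-fold higher in the parotid than on the submandibular-labelled array. Prp2, another proline-rich protein gene, was at least 3145-fold higher and Amy2a3, an amylase, at least 2657-fold higher. Crisp3, a cysteine-rich secretory protein, was 2090-fold higher and Aplnr, the apelin receptor, 1382-fold higher. Zfp831, a name that rests on an old identifier in the file, was 2452-fold higher, but its log2 difference of -11.26 was -5.42 with the median of its probes. The amylase genes and Amy2-ps2, an amylase pseudogene (1404-fold higher), are near-identical copies, so their probes may not separate them. The Dnase1 probe lay on chromosome 10 from 11762599 to 11762658 (rn4) and the Cst5 probe on chromosome 3 from 138971783 to 138971842 (rn4).

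The gene lists fixed before the data were examined showed the same contrast. Of 11 serous secretory products compared, 8 were at least 4-fold lower on the submandibular-labelled than on the parotid array and none was 4-fold higher, with a median difference of -5.50 on the log2 scale. Pip, the prolactin-induced protein of saliva, was 421-fold lower, the proline-rich glycoprotein gene Prb3 381-fold lower and Oprpn 45.2-fold lower. Of 13 mucins and mucous cell factors, 9 were at least 4-fold higher and 1 at least 4-fold lower (median 3.75). Besides Muc19, Agr2 and Bpifb2, these included Agr3 (at least 37.8-fold), a paralog of Agr2, and Itln1 (at least 17.4-fold), an intestinal lectin. Tff3 is 1 of the 9, on an uneven spot, with its other probe not well above background. The member lower than in the parotid, named after its values were seen, was Muc5b, a gel-forming mucin (at least 4.46-fold, and at least 5.72-fold on the sublingual array). Of 23 enzymes and transporters of mucin-type O-glycosylation, 9 were at least 4-fold higher and 2 at least 4-fold lower (median 1.38). Gcnt3, which makes core branches of mucin glycans, was at least 92.0-fold higher, the sialyltransferase St3gal4 65.8-fold higher and the sialyltransferase St3gal1 at least 25.7-fold higher. Galnt5 and Galnt7, which start mucin-type O-glycans, were at least 21.2-fold and 18.9-fold higher. The medians of the serous list lay below, and those of both mucous lists above, all of 10000 random lists of the same size matched on mean expression.

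Products of the granular convoluted ducts, which in the male rat are a feature of the submandibular gland, were not higher as a list than in the parotid on the array that carries that label, and were slightly higher than in the sublingual gland. Of 15 compared with the parotid, none was at least 4-fold higher on the submandibular-labelled array, 2 were at least 4-fold lower and 13 differed by less, with a median of -0.33 (percentile 6.08 among random lists). The members at least 4-fold lower were Smr3a and Fgf2, a fibroblast growth factor (at least 12.0-fold). Smr3b, a salivary prohormone gene, was at -2.66 on the submandibular-labelled array, at least 1.62-fold higher than in the parotid and at least 2.11-fold higher than in the sublingual gland. Against the sublingual array, 10 of 12 compared products were higher on the submandibular-labelled array, none by 4-fold, with a median of sublingual minus submandibular-labelled of -0.39 (percentile 0.00). The following members were chosen after their values were seen, as examples of the list's usual products. The kallikrein gene Klk1 was at 7.54 in the parotid, 7.72 on the submandibular-labelled array and 7.37 in the sublingual gland, and Klk1b3, another kallikrein gene, at 8.14, 8.35 and 7.97. Egf, epidermal growth factor, was at 2.62, 2.02 and 1.61. Kallikrein genes are near-identical copies, so their probes may share signal.

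**Figure D2:**
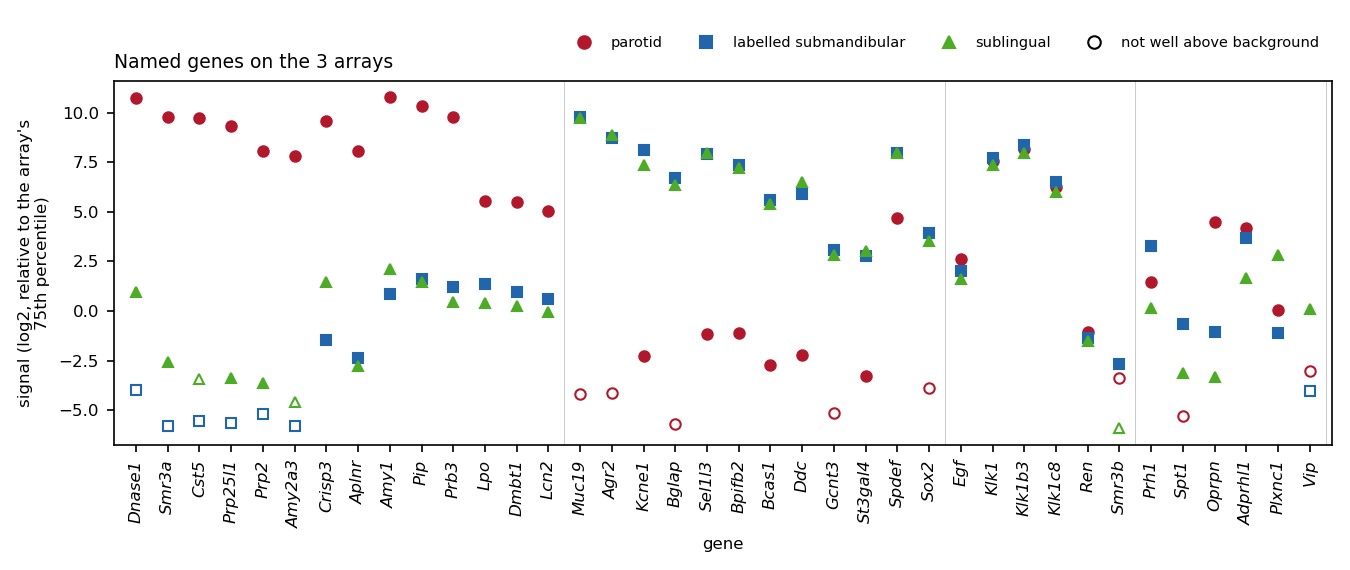
Level (log2, relative to the array's 75th percentile) of named genes on the parotid (circles), submandibular-labelled (squares) and sublingual (triangles) arrays, 1 array each, with open symbols where the probe was not well above background. Squares and triangles lie close together in the mucous block (Muc19 at 9.80 and 9.71), far from the circles, and Klk1 (7.54 to 7.72 and 7.37) shows 3 nearby symbols.

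The sublingual array showed the same contrast with the parotid. Muc19 was at least 9041-fold and Agr2 at least 5141-fold higher than in the parotid, and Cst5 was at least 9148-fold and Prp25l1 6641-fold higher in the parotid. In all, 332 of 10926 compared genes were at least 4-fold higher on the sublingual array and 312 at least 4-fold higher on the parotid array, of which 82 and 109 are lower bounds. With normexp background correction these counts were 215 and 135, and with centring on the median 432 and 234. The 10 genes with the largest folds over the parotid were the 10 named for the submandibular-labelled array. Bglap was at least 891-fold, Kcne1 786-fold, Sel1l3 546-fold, Ddc 427-fold and Bpifb2 310-fold higher. Bcas1 was 271-fold, Kntc1 244-fold and Fam3d 221-fold higher. Of the 10 genes with the largest folds in the parotid over the sublingual array, 8 were shared with the other comparison. Smr3a was 5254-fold, Prp2 3280-fold, Zfp831 2758-fold and Aplnr 1840-fold higher in the parotid, and Amy2a3 at least 2968-fold higher. With the median of their probes, the log2 differences from the parotid were -5.62 for Zfp831 (-11.43 with the brightest probe) and 5.996 for Sel1l3 (9.09). Dnase1 was 875-fold higher, Prb3 642-fold higher, and Duox1, an oxidase that makes hydrogen peroxide, at least 853-fold higher.

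Of 11 serous secretory products, 8 were at least 4-fold lower on the sublingual than on the parotid array (median -5.82), and of 13 mucins and mucous cell factors 8 were at least 4-fold higher (median 3.31) and 1 at least 4-fold lower. Of 23 genes of mucin-type O-glycosylation, 9 were at least 4-fold higher and 3 at least 4-fold lower (median 1.12). Agr3 was at least 72.2-fold, Gcnt3 at least 76.2-fold and St3gal4 79.8-fold higher, while Gcnt1, a core branching enzyme, was 9.68-fold lower. The serous median lay below, and both mucous medians above, all of 10000 random lists. Of 14 granular duct products none was at least 4-fold higher and 2 were at least 4-fold lower on the sublingual array (median -0.70, percentile 0.13).

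Both arrays shared most of their difference from the parotid. Of 10805 genes compared in both, 267 were at least 4-fold higher and 241 at least 4-fold lower than the parotid on both arrays, and none was 4-fold apart in opposite directions. Independent lists of these sizes would share 9.32 and 8.78 genes. The parotid array is common to both comparisons, and part of the overlap may come from the shared array. Compared with both other arrays at once, 241 genes were at least 4-fold higher in the parotid. Cst5, Prp25l1, Smr3a, Prp2, Amy2a3, Zfp831, Aplnr, Dnase1, Amy2-ps2 and Agt led them. Agt, angiotensinogen, was at 6.22 in the parotid, -2.74 on the submandibular-labelled and -2.57 on the sublingual array.

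Among transcription factors of gland development, Sox2 was the member furthest above the parotid, at least 168-fold on the submandibular-labelled and at least 126-fold on the sublingual array. Nkx2-3 was at least 14.1-fold and at least 11.7-fold higher, and Spdef, a regulator of mucous cell differentiation, 9.83-fold and 9.93-fold. Meis2 was 11.6-fold and 12.5-fold lower, and Foxc1 6.68-fold and 9.06-fold lower. Of 46 compared, 5 were at least 4-fold higher and 2 at least 4-fold lower on the submandibular-labelled array, and 7 and 3 on the sublingual array, with medians of 0.19 and -0.12 inside the central 95% of random lists, of which the sublingual one turned to 0.13 under another processing choice. Gata3 (4.39-fold) is 1 of the 7, on an uneven spot of the sublingual array. Antimicrobial and innate defence genes were lower as a list than in the parotid, with 7 of 20 at least 4-fold lower and 2 at least 4-fold higher on each array (medians -1.19 and -1.23, each below all 10000 random lists). Dmbt1, a scavenger glycoprotein of saliva, was 23.5-fold and 38.5-fold lower, and Lcn2, lipocalin 2, 21.5-fold and 34.1-fold lower. Cd14, a receptor for bacterial lipopolysaccharide, was 11.3-fold and 9.34-fold higher, and the oxidase gene Duox2 at least 10.3-fold and at least 9.13-fold higher.

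Genes of ion and water transport differed little. Of 26 compared, none was at least 4-fold higher and 1 at least 4-fold lower on each of the submandibular-labelled and sublingual arrays (medians -0.35 and -0.41, percentiles 2.72 and 1.72). The list of secretagogue receptors had medians of 0.12 and 0.07 at percentiles 66.5 and 67.7, and the first turned to -0.01 under another processing choice. In it the muscarinic receptor Chrm3 was 4.84-fold and 5.51-fold higher than in the parotid. Secretory pathway and unfolded protein response genes had medians of 0.21 and 0.18 at percentiles 28.6 and 11.0, with 1 of 38 at least 4-fold higher on each array, the coat protein gene Sec23b (8.61-fold and 7.34-fold). Genes of mitochondrial respiration had medians of 0.44 and 0.55 (percentiles 80.6 and 77.8), and no member of 38 reached 4-fold. Housekeeping genes had medians of 0.30 and 0.29 (percentiles 48.0 and 28.1). Exocrine pancreas enzymes had medians of -1.02 and -1.04 over 9 compared genes (percentiles 0.37 and 0.50), led by Amy2a3 and by Rnase1, a ribonuclease 19.6-fold and 20.2-fold lower, while Gp2, a zymogen granule glycoprotein, was at least 43.1-fold and at least 37.1-fold higher.

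Markers of other cell types differed with the glands. Myoepithelial and basal cell markers were above the parotid on the submandibular-labelled array for 9 of 10 genes (median 1.53, above all random lists) and on the sublingual array for 8 of 9 (median 1.28, percentile 99.9). Cnn1, calponin of contractile cells, was 9.18-fold and 6.48-fold higher, while Des, desmin, was 5.31-fold and 5.34-fold lower. Duct epithelium markers had medians of 0.72 and 0.69 (percentiles 98.9 and 88.9), with the tight junction gene Cldn4 3.68-fold and 4.02-fold higher. Immune cell markers were lower than in the parotid for 22 of 24 genes on each array (medians -1.12 and -1.08, below all random lists), including Jchain of antibody-secreting cells (4.58-fold and 3.43-fold lower). Cd52, a leukocyte surface protein, went the other way (at least 12.4-fold and at least 16.9-fold higher). Fibroblast and matrix genes had medians of -0.61 and -0.65 (percentiles 0.00 and 0.03), with the matricellular gene Postn at least 12.3-fold and at least 13.8-fold lower. Proliferation genes had medians of -1.02 and -0.87 (percentiles 0.00 and 0.12), and none of 21 reached 4-fold. Endothelial markers had medians of -0.84 and -1.04 (percentiles 0.43 and 0.10), and none of 13 reached 4-fold.

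Adipocyte markers had medians of -0.66 and -0.47 (percentiles 0.35 and 3.99). Skeletal muscle markers had medians of 0.11 and 0.17 (percentiles 73.6 and 84.7), nerve and Schwann cell markers -0.79 and 0.06 (percentiles 0.56 and 83.5), and blood cell markers -0.56 and 0.20 over 5 and 6 genes (percentiles 4.22 and 70.7). The signs of both skeletal muscle and both blood cell medians, and of the sublingual median of the nerve list, turned under at least 1 other processing choice. The nerve list was split, with 6 of 15 compared genes above the parotid on the submandibular-labelled and 8 of 16 on the sublingual array. Compared directly, its median of sublingual minus submandibular-labelled was 0.10 (percentile 91.4). In the nerve list, Npy, neuropeptide Y, was 15.4-fold and 13.2-fold higher than in the parotid. These lists stand for cells that a dissected gland can hold besides its secretory cells.

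**Figure D3:**
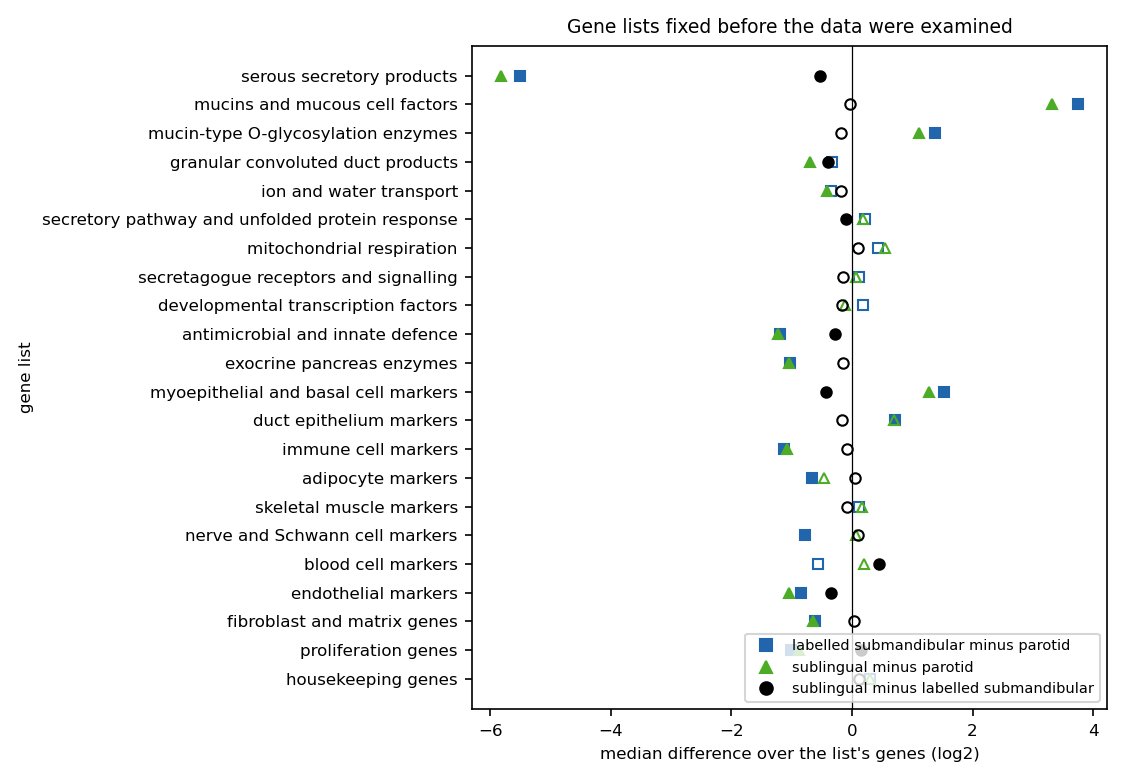
Median difference (log2) over the compared members of each of 22 gene lists, for the 3 pairs of arrays. Filled symbols lie outside the central 95% of 10000 random lists matched on mean expression; serous products lie at -5.50 and -5.82 against the parotid, and mucous factors at 3.75 and 3.31.

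Between the sublingual and submandibular-labelled arrays few genes differed. Of 10487 compared, 16 were at least 4-fold higher on the sublingual array and 8 on the submandibular-labelled array (0.229% together), and with normexp background correction 7 and 4. Levels of the leading mucous genes were close. Muc19 was at 9.80 on the submandibular-labelled and 9.71 on the sublingual array, Agr2 at 8.71 and 8.89, and Spdef at 7.96 and 7.98. Salivary products were among the genes that differed. Prh1, annotated in the file as a glutamine- and glutamic acid-rich salivary protein, was 8.61-fold higher on the submandibular-labelled array, Spt1, a salivary protein gene, 5.60-fold higher, and Oprpn, annotated in the file as submandibular salivary mucin 10, 4.87-fold higher. Oprpn was highest in the parotid, at 4.47 against -1.03 and -3.31. Adprhl1 was 4.13-fold higher on the submandibular-labelled array. With normexp background correction Prh1 stayed at least 4-fold apart, while the log2 differences of Spt1 (-1.09), Oprpn (-0.91) and Adprhl1 (-1.94) did not reach that size. On the sublingual array, Dnase1 was at least 22.9-fold higher than on the submandibular-labelled array, Crisp3 7.59-fold, Plxnc1, a semaphorin receptor, 15.1-fold, Vip, vasoactive intestinal peptide, at least 12.8-fold, and Sycp3l2 at least 9.83-fold higher. Vip (1.72) and Sycp3l2 (1.86) were under 4-fold with normexp background correction, and Plxnc1 (1.87) with the median of its probes. The other probe of Plxnc1 was not well above background on any array. Gys2, a glycogen synthase gene named after its values were seen, was the 1 gene of the 24 with a pair of probes well above background on all 3 arrays, and both were at least 4-fold higher on the sublingual than on the submandibular-labelled array (2.29 and 2.01 on the log2 scale; 1.95 for the brighter with normexp background correction).

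Several of the remaining differences rest on 1 uneven spot. The bright spots of Or4a66b and Or2aj4 (at least 26.5-fold and 26.3-fold higher on the sublingual array), Cacna2d4 (at least 18.8-fold), Tle4 (at least 11.2-fold) and Gata3 (at least 6.70-fold) had a pixel variation above the 95th percentile of 500 spots of nearest brightness. The same held on the submandibular-labelled array for Or52p2 (at least 30.8-fold higher there), Tff3 (at least 25.3-fold) and Ndst3 (at least 5.02-fold). The other probe of Tff3 was not well above background on any array. Compared with both other arrays, 5 genes were at least 4-fold higher on the submandibular-labelled array, and Spt1 was the member without an uneven spot. Or52p2, Tff3 and Ndst3 were among the others. On the sublingual array 10 genes were at least 4-fold higher than on both other arrays. Against the nearer of the others, Vip was at least 8.69-fold, Plxnc1 6.77-fold, Sycp3l2 at least 8.91-fold and Kif19b 5.83-fold higher. Their spots were not above the 95th percentile of pixel variation, though that of Vip was close to it (percentile 93.2). Those of Or4a66b, Or2aj4, Cacna2d4, Tle4 and Gata3 were above it.

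Of the gene lists, the serous one held the most members 4-fold apart between these arrays, 3 of 10 (Dnase1, Prh1 and Oprpn). In the mucous list, 11 of 12 compared genes differed by less than 4-fold (median -0.04, percentile 34.4), and in the O-glycosylation list all 23 did (median -0.19, percentile 3.18). The sublingual median lay below the submandibular-labelled one in the serous (-0.53, with 1 of 10 at least 4-fold higher and 2 at least 4-fold lower), granular duct (-0.39, none of 12 at 4-fold), myoepithelial (-0.43), antimicrobial (-0.28), endothelial (-0.34) and secretory pathway (-0.10) lists, each under percentile 2.5. Blood cell markers (0.45, percentile 99.0) and proliferation genes (0.14, percentile 98.6) lay above it. The other lists, with medians from -0.18 to 0.11, were inside the central 95% of random lists. Random lists do not keep together genes that vary together, and the percentile measures no spread over arrays. Over all pairs of arrays, 33 of 66 list medians lay outside the central 95%.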

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

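Of the tests in this part, those on granular duct products, on diluted sublingual genes and on carried-over parotid tissue were chosen only after the result was seen, as was the control for probe brightness. Probes matched to no single gene carry signal that the comparisons above leave out. Of 20358 such probes left once spots with an outlier flag were left out (20364 before), 7912 were well above background on all 3 arrays. On each array 0 of 153 negative control spots were, which does not show what the unmatched probes bind. Of these unmatched probes, 218 were at least 4-fold higher on the submandibular-labelled than on the parotid array and 347 lower, 226 were higher and 273 lower on the sublingual than on the parotid array, and 13 were higher and 8 lower on the sublingual than on the submandibular-labelled array. Examples chosen after their values were seen are given by the file's own descriptions. A target described as carbonic anhydrase VI was at 10.08 in the parotid, 1.19 on the submandibular-labelled and 0.15 on the sublingual array. A target whose description names both "lectin, mannose-binding, 1 like" and complexin III was at -0.64, 8.79 and 9.11.

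The submandibular-labelled and sublingual arrays were almost alike. That 1 labelled RNA was put on both arrays, with only spot noise between them, is argued against. The small differences between these arrays were compared for 2164 genes with several probes well above background. They correlated with r = 0.464 between a gene's brightest and next brightest probe, where spot noise alone would give a value near 0. The correlation was 0.456 once the median difference at each probe's brightness was taken out. Hybridisation differences that act on both probes of a gene were not covered, nor was 1 RNA labelled separately for each array. No pair of arrays with the same RNA was at hand to measure them. Whether there was sublingual tissue or RNA in the submandibular-labelled sample cannot be told apart from a true likeness of the glands: 0 of 22 granular duct products were at least 4-fold higher there than on both others, but only 11 were well above background there, and this was the observation that raised the question. Other values ran the way the label says. Of granular duct products, 10 of 12 were higher on the submandibular-labelled than on the sublingual array (median of sublingual minus submandibular-labelled -0.39). These 10 are not independent: they include the kallikrein genes Klk1, Klk1b3, Klk1c2, Klk1c6 and Klk1c8, whose probes may share signal. They also include Igf1, which was almost level (-0.01). Prh1 (8.61-fold), Spt1 (5.60-fold) and Oprpn (4.87-fold) were higher on the submandibular-labelled array too. The last pair was under 4-fold with normexp correction (-1.09 and -0.91 on the log2 scale, sublingual minus submandibular-labelled). That shift was not particular to the granular duct list. The serous (-0.53), myoepithelial (-0.43), antimicrobial (-0.28) and endothelial (-0.34) medians were also lower on the sublingual array. Blood cell (0.45) and proliferation (0.14) medians were higher there. Oprpn was highest in the parotid, at 4.47. A sample mostly of submandibular tissue with a smaller part of sublingual tissue stays open too, since the median difference of 0.077 over 58 genes at least 16-fold higher in the sublingual than in the parotid array could count against it only if submandibular tissue lacked these genes, which no array here shows.

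Dnase1 and Crisp3, both highest in the parotid, were at least 22.9-fold and 7.59-fold higher on the sublingual than on the submandibular-labelled array, while 7 of 10 serous products were lower there (median -0.53). Parotid tissue in the sublingual sample would bring all parotid transcripts at 1 share, which Dnase1 puts at 0.111% and Crisp3 at 0.315% of the parotid level. Of 11 other genes at least 100-fold higher in the parotid whose implied level could be measured, 63.6% lay on the sublingual array more than 1 log2 unit below the level that the lower share implies, among them Smr3a (-2.58 against an implied -0.05) and Prp25l1 (-3.35 against -0.47). Amy1 (2.15 against an implied 0.94) and Amy2-ps2 (0.97 against 0.23) lay above that level, and higher than on the submandibular-labelled array (0.88 and -0.41). Pip and Prb3 lay above it too, but lower than on the submandibular-labelled array. Smr3a was at least 1.99-fold higher on the sublingual than on the submandibular-labelled array. Prp25l1 and Prp2 were well above background on the sublingual but not on the submandibular-labelled array, near the lowest well-measured level. Aplnr (-2.76 against -2.35) and Zfp831 (-3.38 against -3.21) were lower on the sublingual array. The lipocalin genes Mup4l3 (-2.21 against -3.39), Mup4l1 (-0.89 against -1.72), Mup4l4 (-0.13 against -0.66) and Mup5 (-0.09 against -0.43) were higher there. Mup4 (-5.96 against -5.78) was lower. Dnase1 and Crisp3 were picked for their difference, so other genes were likely to fall below their share. The values argue only against parotid tissue of ordinary composition at the share Dnase1 implies as the whole cause. A smaller share, and a difference between the glands' own cells, stay open and were not tested.

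Of 24 genes at least 4-fold apart between the submandibular-labelled and sublingual arrays, 21 had 1 probe. Local defects of spots may account for some of them: 10 had a bright spot whose pixel variation was above the 95th percentile of 500 spots of nearest brightness, where 1.20 would be expected. The number lies between what a common technical cause and its absence would have needed, so the cause of the set as a whole cannot be told apart. The spots of the other 14, among them Prh1, Spt1, Oprpn, Dnase1 and Vip, were not above the 95th percentile. Those of Vip (percentile 93.2) and Rpl39l1 (93.4) lay close to it.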

How the results depend on the processing

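The tests with every target, without the submandibular-labelled array and without genes of uneven spots were chosen after seeing the data. No paired analysis was possible because each gland had 1 array and no animal is named. Signal over background limits the counts: 77 of 313 and 103 of 304 folds between the submandibular-labelled and parotid arrays are lower bounds, as are 10 of 16 and 4 of 8 between the sublingual and submandibular-labelled arrays.

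Over the processing choices tried, the correlation of the submandibular-labelled with the sublingual array stayed between 0.989 and 0.992, and those with the parotid array between 0.919 and 0.943. No list median outside the central 95% of random lists changed sign (33 medians), and no named difference reversed. All 40 named differences from the parotid were at least 4-fold under each of the 6 choices tried for them, but only 7 of 17 between the sublingual and submandibular-labelled arrays were. Of the other 10, 8 fell under 4-fold with normexp correction (Vip, Tle4, Sycp3l2, Gata3, Spt1, Ndst3, Oprpn and Adprhl1) and 2 with the median of the probes (Plxnc1 and Tff3). Of the list medians, 271 values moved by less than the spot error and 125 by more. Among them, the serous median of sublingual minus parotid ranged from -7.78 to -4.75 and the mucous median of submandibular-labelled minus parotid from 2.41 to 5.31. The sizes of named differences moved by more than the spot error in 167 values and by less in 175. Normexp correction moved 56 of 57, by the construction given below. Of the counts, 56 values stayed within 1.5 times the main count and 67 moved further. No spot was saturated, so leaving out saturated spots could change nothing. Centring on the median kept the counts within that limit but moved their balance: 67.0% of the genes 4-fold apart were then higher on the submandibular-labelled than on the parotid array (435 against 214; 50.7% in the main analysis), and 64.9% higher on the sublingual array (432 against 234; 51.6%).

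The values that moved are given as genes higher on the submandibular-labelled than on the parotid array, and the reverse; on the sublingual than on the parotid array, and the reverse; on the sublingual than on the submandibular-labelled array, and the reverse; and then higher than on both others in the parotid, submandibular-labelled and sublingual arrays. With normexp correction they were 196, 134, 215, 135, 7, 4, 120, 3 and 4. The offset shrinks folds of dim genes by construction. Counting probes instead of genes gave 588, 700, 618, 637, 34, 17, 513, 11 and 16. A threshold of 2-fold gave 1191, 1203, 1360, 1344, 102, 61, 952, 18 and 41, and one of 10-fold gave 95, 109, 96, 120, 8, 3, 105, 3 and 4. Counting every target, matched to a gene or not, gave 525, 649, 550, 581, 28, 16, 473 and 11, without the last count. These 4 choices change what is counted.

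Where both sides had to be well above background, which leaves out every lower bound, 201 and 203 genes were higher in the parotid than on the submandibular-labelled and sublingual arrays, 6 and 4 differed between these arrays, and 143, 0 and 2 were higher than on both others. With no filter on dim genes, 616 and 677 were higher in the parotid, 54 and 43 differed between the other arrays, and 418 (parotid) and 11 (submandibular-labelled) were higher than on both others. With measured differences in place of bounds, 500 and 490 were higher in the parotid, 39 and 18 differed between the other arrays, and 8 were higher on the submandibular-labelled than on both others. Dim signals then enter the folds by construction. Without the submandibular-labelled array, 332 genes were higher on the sublingual array than on the other array left, the parotid. Without genes of uneven bright spots, 10 and 4 genes differed between the sublingual and submandibular-labelled arrays, and 1 (submandibular-labelled) and 4 (sublingual) were higher than on both others.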

Other observations

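The following was chosen after the data were seen. Genes higher in the parotid than on both other arrays lay near each other more often than random genes. Of 236 such genes with a position (rn4, from the files), 35 lay in 9 groups of at least 3 genes with gaps of at most 500 kb, against a median of 9 genes and a highest value of 28 in 1000 random draws of as many compared genes. On chromosome 4 a group held the proline-rich protein genes Prb1, Prpmp5, Prb3, Prp2 and Prp25l1, with probes from 169556030 to 169790334. Their parotid minus sublingual differences were 5.82, 4.60, 9.33, 11.68 and 12.70 on the log2 scale. On chromosome 5, from 78090663 to 78820573, another held the lipocalin genes Obp3, Mup4l4, Mup4, Mup5, Mup4l1 and Mup4l3, known for carrying pheromones and odorants, with differences of 4.30 to 6.10. Other groups held the amylase genes Amy2-ps2, Amy2a3 and Amy1 on chromosome 2, Lcnl, Vegp2 and Lcn1 on chromosome 3, Pip and Sval2 on chromosome 4 near 69637626, and Rnase1l1 and Rnase1 on chromosome 15. These 6 groups also held Ybx3, Glal, Slc31a2, Kel and Slc39a2. The other 3 groups were Dnase1, Mefv and Or1f27 on chromosome 10, Rps7, Tnfrsf25 and Rnf207 on chromosome 5, and Akap5, Hspa2 and Ppp1r36 on chromosome 6. Members of such families are copies of each other, and probes that bind several of them would add to these groups. The random draws did not keep families together and no other gene set was compared, so nearness beyond that of gene families was not tested.

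Some abundant transcripts differed between the submandibular-labelled and sublingual arrays by less than 4-fold. The ribosomal protein genes Rps18, Rpl13a and Rpl32, 3 of the housekeeping list, were 1.06, 0.81 and 0.79 higher on the log2 scale on the sublingual array, and the respiratory genes Cox6c and Cox7a2 0.86 and 0.83 higher, while Actb was 0.43 lower there (-0.43). Their lists did not share this: Rplp0, the other ribosomal protein gene of the housekeeping list, was 0.10 higher, and the respiration list had a median of 0.09 with 16 of 38 members lower on the sublingual array. Rps18 was at 9.84 in the parotid, 8.60 on the submandibular-labelled and 9.66 on the sublingual array.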
